A study of Mus musculus with 42 samples.

How the data were processed

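RNA sequencing was used on mouse bone marrow-derived macrophages of 2 genotypes, WT and MS4A4A KO. Per the labels, the cells were detached, plated again and used the next day, with RNA taken from untreated cells or 2, 8 and 24 h after 1 µM Dex or vehicle, and libraries were made with a SMART-Seq mRNA kit. This gives 14 groups of 3 libraries, and each library was put in its group from its title.

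The deposited table holds expected counts of 11160 genes in 42 libraries, by gene symbol. Per the submitters' processing notes, fastp, HISAT2, Salmon and the GRCm38 assembly were used, with no version, role or order given, and the annotation and the rule that selected the genes are not given in the sources used here. Of 468720 deposited expected counts, 69.5% lie within 0.01 of a whole number. The lowest total of a gene over all libraries is 256 counts, so low genes are missing from the table and members of the gene lists that are not in it were not analysed here. Salmon-type estimates share reads between similar transcripts, so values of close paralogs depend on that split, and whether the counting used strand is not given, so overlapping genes on opposite strands are uncertain too.

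The expected counts were rounded to whole numbers for the tests. No column of the table was left out. The 42 libraries hold 10140200 to 33528400 counts (median 27998700), with 11135 to 11159 of the genes having a count, 17.3 to 20.2% of counts in the top 10 genes and 0.553 to 1.12% in mitochondrial transcripts. Scaling factors (TMM) lie between 0.950 and 1.04. The median SE of a log2 fold change was between 0.117 and 0.119 for comparisons of 2 groups. Replicates of each group differed by more than counting noise in a chi-square test over genes, so none was taken as the same library deposited again. That test does not show whether they came from separate cultures. Counting intervals and floors, where given, cover counting error only.

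The tests were edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on a single model with 14 group means over all 42 libraries, with TMM scaling and Benjamini-Hochberg adjustment over all genes within a comparison, called at an adjusted p of 0.05. The filter on low counts (filterByExpr) removed 0 genes. Comparisons were KO against WT within each condition and averaged over the 4 conditions without Dex, Dex against vehicle at each time within each genotype and averaged over the genotypes, the difference of the Dex effect between KO and WT at each time and averaged over the times, and vehicle against untreated cells at each time. CPM are TMM-scaled. The size of the response was the median difference between KO and WT over the genes called in the average of the genotypes, each signed by its average change, tested with fry (limma 3.58.1) and with an exact two-sided permutation test of scores per library, permuted within treatment.

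The 36 gene lists cover glucocorticoid action, macrophage phenotype, inflammation, interferon, antigen presentation, metabolism, stress, cell cycle, the Ms4a family, other cell types, sex-linked genes and strain differences. They were tested with limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01 when at least 5 members were measured, adjusted over the lists of a comparison. Of the 159 list calls over all comparisons, 16 held with an estimated correlation. Counts of members are given over all genes and adjusted over the list alone. The genes named are Ms4a4a, the 5 highest and 5 lowest called log2 fold changes with at least 5 CPM in a group, without overlap between replicates where 2 groups are compared and without unnamed loci, up to 4 members of a list with the lowest p, and Nr3c1, Fkbp5, Tsc22d3, Per1, Dusp1, Zbtb16, Klf9, Cd163, Mrc1, Mertk, Il1b, Tnf, Il6, Ccl2, Nos2 and the other Ms4a genes; any other is said to be chosen after its values were seen, as are members named because they moved against their list. Groups, comparisons, tests, lists, this rule and most alternatives were set before the data were examined.

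Replicate numbers of the labels were checked as pairs by the correlation of same-numbered libraries' deviations from their group means. Every correlation was over 0.1 for KO against WT after 2, 8 and 24 h of vehicle (lowest 0.239, 0.229 and 0.227) and after 2 h of Dex (0.254), for Dex in WT at 8 and 24 h (0.294 and 0.256) and for Dex in KO at 2 and 8 h (0.122 and 0.111), so the numbers were taken as pairs there and a fit with the replicate number as a block was set beside the result where it changed a call.

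Coordinates are from GENCODE mouse release 21 (GRCm38), in which 10745 of the 11160 symbols (96.3%) have a single place. Alternatives were DESeq2 1.42.0, median-ratio scaling, no filter, a mean of at least 5 CPM, the replicate block, a fit on the compared libraries alone, a prior count of 0.5, an estimated correlation and leaving out each library in turn. On simulated counts of 11160 genes with 200 changed, 70.1, 89.6 and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered for Dex in WT at 8 h (2.82% false calls), 29.9, 79.1 and 98.5% for the interaction at 8 h (5.48%), and 98.5, 100 and 100% for KO against WT averaged without Dex (6.13%). The test of response size gave 0 of 5 simulated equal responses under 0.05 and -0.119 where the KO response was set to 0.8 of the WT response. All simulated libraries were drawn independently, without sets of a genotype and replicate number. The rates of false calls therefore do not cover such sets, which matter for KO against WT averaged without Dex.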

Results

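Expression of 11160 genes was measured by RNA sequencing in mouse bone marrow-derived macrophages, cells grown from bone marrow precursors with the growth factor M-CSF. Wild-type cells (WT) were set beside cells with a knockout of MS4A4A (KO), a membrane protein of the MS4A family found on macrophages. After replating, the cells were taken untreated, or after 2, 8 or 24 h with vehicle or with 1 µM dexamethasone (Dex), a synthetic agonist of the glucocorticoid receptor. The design asks whether loss of MS4A4A changes how macrophages respond to a corticosteroid. The 14 groups held 3 libraries each, 42 in all, and the libraries had 10140200 to 33528400 estimated counts (median 27998700). The labels do not say whether the replicates of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

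Ms4a4a, the gene targeted in the KO, was lower in KO than in WT libraries, but its transcript remained measurable in every KO library. It lies on chromosome 19 of GRCm38, from 11375523 to 11392790 on the plus strand, and is annotated as protein-coding. In untreated cells it stood at 89.1 ± 6.36 CPM (counts scaled to library size; mean ± SD, n = 3) in WT and at 46.7 ± 2.69 CPM in KO. After vehicle the WT and KO levels were 84.8 ± 5.56 and 34.5 ± 3.40 CPM at 2 h, 72.9 ± 6.61 and 28.9 ± 5.54 CPM at 8 h, and 168 ± 39.1 and 108.5 ± 64.3 CPM at 24 h. Dex raised the gene in both genotypes, to 116 ± 10.5 and 72.1 ± 6.65 CPM at 2 h, 631 ± 30.2 and 390 ± 29.4 CPM at 8 h, and 1587 ± 92.0 and 765 ± 31.7 CPM at 24 h, although the rise in WT at 2 h did not pass the test (adjusted p = 0.217, edgeR quasi-likelihood, Benjamini-Hochberg). Averaged over the 4 conditions without Dex, the KO level was 0.484 of the WT level, with a log2 difference of -1.05 ± 0.11 (SE; adjusted p = 3.01e-07, edgeR quasi-likelihood, Benjamini-Hochberg; 12 libraries a side). With the counts summed over these conditions into 3 sets a side it was -0.96 ± 0.20 and did not pass (adjusted p = 0.9998, edgeR quasi-likelihood, Benjamini-Hochberg). The labels do not give the part of the gene that was removed, so counts over the whole gene do not show whether the remaining transcript is intact.

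**Figure D1:**
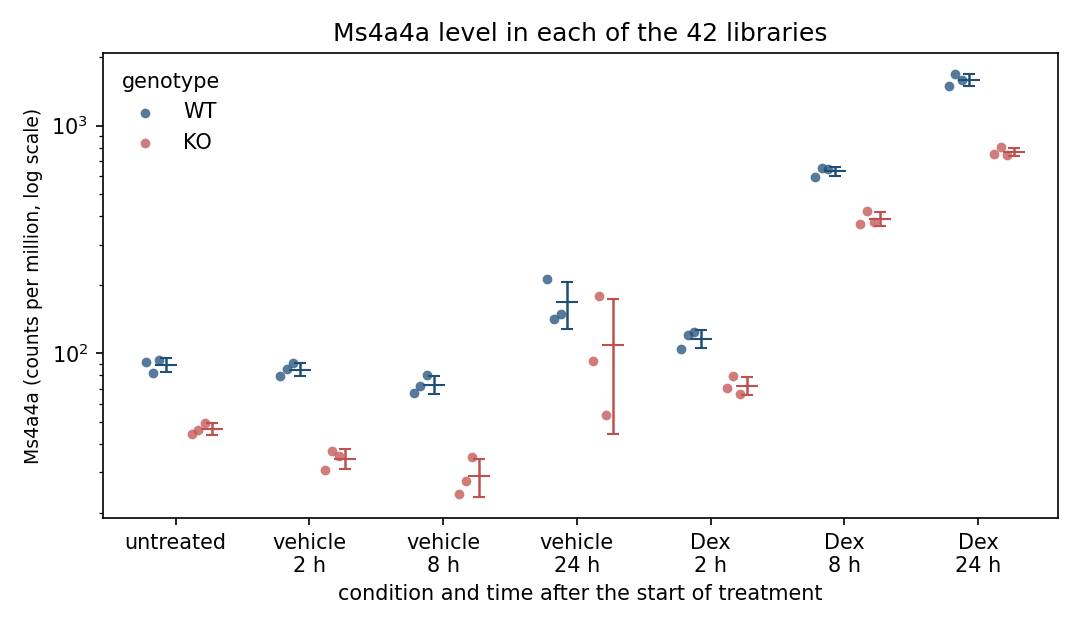
Ms4a4a in CPM on a log axis, with a point for each library and the mean ± SD of the 3 libraries of each group, for WT and KO in the 7 conditions. KO libraries lie below WT libraries of the same condition except after 24 h of vehicle, where the KO libraries run from 53.5 to 179 CPM and overlap the WT libraries.

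Which genes differed between KO and WT before any steroid was asked by averaging the KO over WT difference across the untreated and the 3 vehicle conditions. With each library taken as a sample of its own, 24 genes differed beside Ms4a4a, 13 higher and 11 lower in KO. Libraries of the same genotype and replicate number may form sets that recur in the 4 conditions, and the calls rest on taking them as separate. With the counts of each set summed, 3 sets against 3, edgeR quasi-likelihood called 0 genes without and 0 with the replicate number as a block. At an unadjusted p under 0.05 stood 363 and 819 genes. All 25 genes had the same direction in both fits, but these use the same libraries and so add nothing on the direction. Fitted on these libraries alone the count was 22. As many genes, up to 1102, came from 6 of the 10 ways to part the 6 sets into groups of 3, the real one included. In 4 of the 10 ways every pair of same-numbered sets was parted. Of these the real one gave 22 genes and the others 5, 2 and 0, with too few ways for a share under 0.05. Ms4a4a itself was not called with the summed counts, so 0 calls there do not show the other genes to be equal. The differences below were called only with each library as a sample of its own, and whether they hold with sets as samples is not settled. Fam177a was 1.71-fold higher in KO (log2 0.78 ± 0.09; adjusted p = 1.06e-05, edgeR quasi-likelihood, Benjamini-Hochberg). Cxcl9, a T cell-attracting chemokine, was higher by 1.40 ± 0.29 on the log2 scale, Cfb, complement factor B of the alternative pathway, by 0.87 ± 0.19, the kinase gene Dmpk by 0.77 ± 0.17 and the chemokine Ccl5 by 0.69 ± 0.15. Cxcl9 was scarce, at 2.56 ± 0.28 CPM in untreated WT and 5.81 ± 3.13 CPM in untreated KO cells. The genes lower in KO were led by Tgtp1, an interferon-inducible GTPase (log2 -1.83 ± 0.40). Tgtp1 and Tgtp2, which was also measured, are similar copies between which the counting could split reads, and their summed counts were not tested. Also lower were Lyrm7, an assembly factor of mitochondrial complex III (-0.75 ± 0.13), Slc36a1, a lysosomal amino acid transporter (-0.63 ± 0.13), and the kallikrein gene Klk1b11 (-0.51 ± 0.11).

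Several of these genes are neighbours on the chromosomes. Srp54a, which encodes a subunit of the signal recognition particle (chromosome 12, 55080262 to 55115367), Fam177a (55124469 to 55142104), Srp54b (55155104 to 55189573) and 1700047I17Rik2 (55199592 to 55217168) adjoin each other, all on the plus strand and annotated as protein-coding. All 4 were higher in KO: Srp54a by 0.65 ± 0.08, Srp54b by 0.43 ± 0.05 and 1700047I17Rik2 by 0.76 ± 0.12 on the log2 scale. Lyrm7, Gpx3, Slc36a1 and G3bp1 lie together on chromosome 11 and went in different directions, Gpx3 lower (-0.37 ± 0.08) and G3bp1 higher (0.14 ± 0.03). Ccl5, Srp54a, Srp54b, 1700047I17Rik2, Gpx3 and G3bp1 were chosen after their values were seen. Srp54a and Srp54b, and likewise Fam177a and 1700047I17Rik2, are similar copies between which the counting could split reads. Since both copies of each pair were higher in KO, their summed counts were too, by 0.50 ± 0.06 and 0.77 ± 0.10.

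Among the gene lists fixed beforehand, the interferon-stimulated genes, transcripts induced by type I and II interferon, had a median above 0 in KO without Dex. None of the 31 members passed over all genes by edgeR quasi-likelihood, 11 were higher and 0 lower adjusted over the list alone, and the median log2 difference was 0.21. The list test with a preset correlation called them (adjusted p = 3.29e-12, limma camera), and the call was lost, with adjusted p = 0.61 with an estimated correlation. The shift was not in every replicate: the mean log2 CPM of the list in KO and WT replicate 2 was 7.07 and 7.18 in untreated cells, 6.50 and 6.67 after 2 h and 4.67 and 5.05 after 8 h of vehicle, against 4.79 and 4.53 after 24 h, and KO was the higher in numbers 1 and 3 in each of these conditions. In untreated cells alone the list was called too (adjusted p = 4.11e-05, limma camera, and adjusted p = 0.925 with an estimated correlation), but not without the libraries numbered 1 (adjusted p = 0.802). The lists of cell cycle genes (median 0.08), macrophage identity (0.06), circadian clock (-0.09) and mitochondrial transcripts (-0.07) were called too, with 0 members passing over all genes and 0, 1, 1 and 0 adjusted over the list alone. Their adjusted p was 0.877, 0.44, 0.61 and 0.877 with an estimated correlation. The cell cycle list changed direction over the conditions: its median was 0.18 in untreated cells and 0.19 and 0.11 after 2 and 8 h of vehicle, but -0.17 after 24 h (limma camera adjusted p = 3.59e-08, 1.60e-05, 0.000959 and 8.33e-05, and at least 0.710 with an estimated correlation). The call on the average was lost without the libraries numbered 3 (adjusted p = 0.669, limma camera), that in untreated cells without those numbered 1 (0.251), and that at 24 h without those numbered 1 or 2 (0.0753 and 0.436). The 24 h value includes KO vehicle 24 h replicate 2, which lay between vehicle and Dex, as described further on. None of the 23 glucocorticoid receptor targets passed over all genes, with 1 higher and 1 lower adjusted over the list alone. The count of 25 genes, 13 higher and 12 lower, came from 933 genes at an unadjusted p under 0.05; DESeq2 called 71, 24 of them shared, and the fit with the replicate number as a block called 111, 48 higher and 63 lower, 25 of them shared. The count fell to 9 without WT untreated replicate 1 or WT vehicle 8 h replicate 3, to 10 without WT vehicle 2 h replicate 3 or KO vehicle 8 h replicate 1, to 11 without KO vehicle 2 h replicate 3, to 12 without WT vehicle 24 h replicate 1, to 14 without KO vehicle 24 h replicate 1, to 15 without KO vehicle 8 h replicate 3, to 16 without KO untreated replicate 3, and rose to 38 without KO vehicle 8 h replicate 2. Ms4a4a, Fam177a, Srp54a, Srp54b, 1700047I17Rik2 and Lyrm7 kept their calls in each of the 24 fits without 1 library, whereas Cxcl9 kept its call in 14, Klk1b11 in 13, Slc36a1 in 16, Ccl5 in 11, Cfb in 10, Tgtp1 in 9, Dmpk in 8, Gpx3 in 5 and G3bp1 in 12 of them. Tgtp1 stood at -3.69 without KO vehicle 24 h replicate 2.

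**Figure D2:**
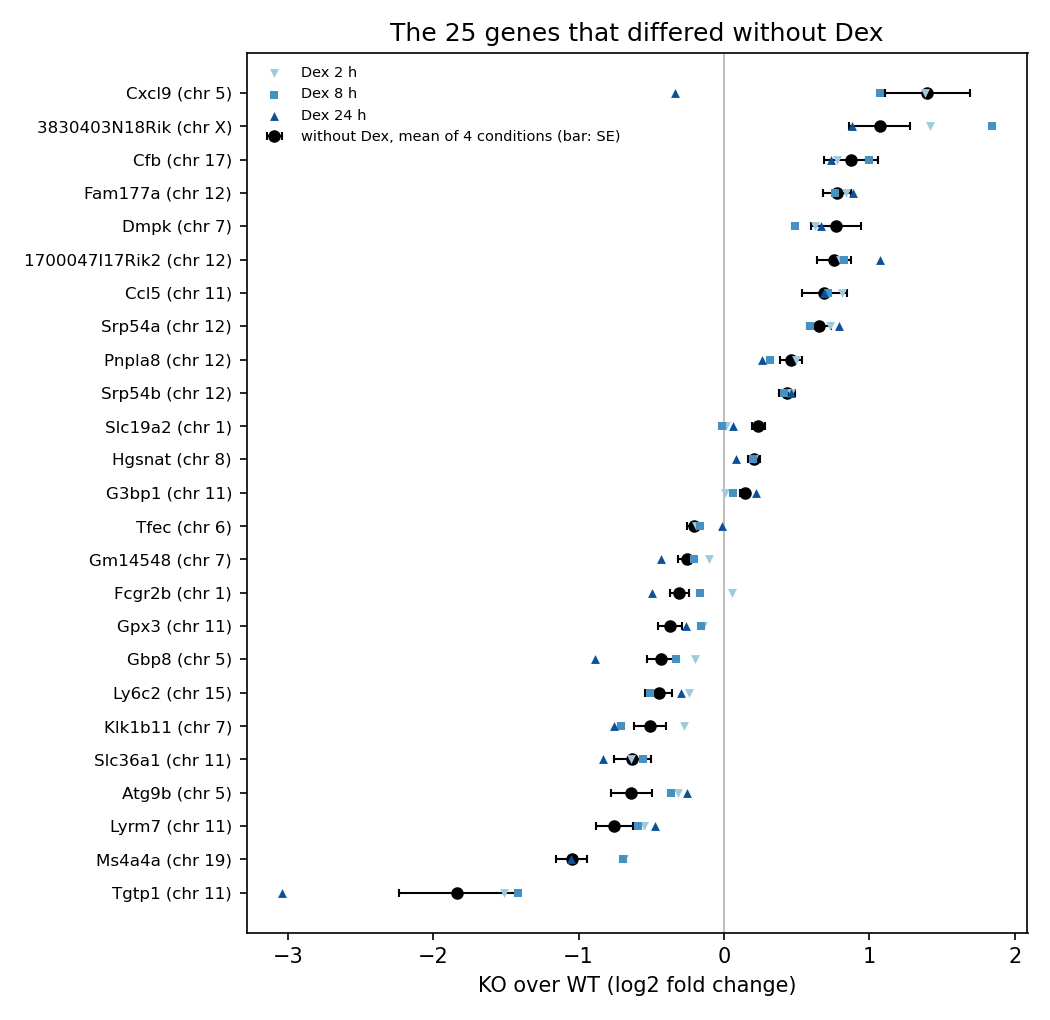
KO over WT log2 fold changes of the 25 genes that differed without Dex, as the mean of 4 conditions with SE bars, beside the same difference after 2, 8 and 24 h of Dex. Apart from Ms4a4a, 23 of the other 24 genes kept their direction at each Dex time, the exceptions being Fcgr2b at 2 h, Slc19a2 at 8 h and Cxcl9 at 24 h.

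Within single conditions the genotypes differed at few genes besides Ms4a4a. After vehicle, Ms4a4a was the gene called at 2 h (log2 -1.30 ± 0.21; adjusted p = 0.00983, edgeR quasi-likelihood, Benjamini-Hochberg; n = 3 a side) and at 8 h (-1.34 ± 0.22; adjusted p = 0.00673). In untreated cells, at 24 h of vehicle and at 2 and 8 h of Dex its differences of -0.93 ± 0.21, -0.63 ± 0.21, -0.69 ± 0.21 and -0.69 ± 0.21 did not pass, and edgeR quasi-likelihood called 0 genes. Genes at an unadjusted p under 0.05 numbered 343, 664, 947 and 177 in these 4 conditions, and DESeq2 called 0, 0, 4 and 0. For vehicle at 2 and 8 h there were 495 and 218 genes at an unadjusted p under 0.05, and DESeq2 called 2 in each. Replicate numbers paired the libraries after vehicle and after 2 h of Dex. With the replicate number as a block, 3830403N18Rik was also higher in KO after 2 h of vehicle (log2 1.24). The block added Fam177a (0.88), Srp54a (0.71) and Srp54b (0.45) after 8 h of vehicle, and Srp54b (0.48) after 24 h. After 2 h of Dex it gave 5 genes higher in KO: 3830403N18Rik (1.33), Fam177a (0.87), Srp54a (0.75), Srp54b (0.46) and Pnpla8 (0.50). These genes were chosen after their values were seen. At 2 h of vehicle the call on Ms4a4a was lost without WT replicate 2 or 3 or without KO replicate 1, 2 or 3, leaving 0 genes each time. At 8 h of vehicle 0 genes were left without WT replicate 3, KO replicate 1 or KO replicate 2, and there were 3 without WT replicate 1. At 24 h of vehicle there was 1 gene without WT replicate 1, KO replicate 1 or KO replicate 2, 3 without KO replicate 3 and 14 without WT replicate 2, and at 2 h of Dex there were 2 without WT replicate 1.

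After 24 h of Dex the genotypes differed at 5 genes. Lpl, the lipoprotein lipase that frees fatty acids from triglycerides, was 1.93-fold higher in KO, at 1678 ± 390 CPM against 870 ± 91.3 CPM in WT (SD, n = 3; adjusted p = 0.0382, edgeR quasi-likelihood, Benjamini-Hochberg). After 24 h of vehicle Lpl had stood at 4253 ± 418 CPM in WT and 4621 ± 1276 CPM in KO. The collagen-binding inhibitory receptor gene Lair1 was higher in KO by 0.46 ± 0.09 on the log2 scale, the stress-induced transcription factor gene Atf3 by 0.45 ± 0.09 and the endoplasmic reticulum co-chaperone gene Dnajc1 by 0.31 ± 0.06. Ms4a4a was lower (-1.05 ± 0.21). Of the 31 interferon-stimulated genes 0 passed over all genes and 0 adjusted over the list alone, with a median of -0.22. Their call by the list test was lost, with adjusted p = 0.711 with an estimated correlation. Unadjusted, 851 genes stood under 0.05, and DESeq2 called 25 genes, 14 higher and 11 lower, so that 56.0% of its calls were higher in KO against 80.0% by edgeR quasi-likelihood. No gene was called without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 2, 1 was without KO replicate 3, and 13 were without WT replicate 2. Ms4a4a kept its call in 0 of these 6 fits, and Lpl, Lair1, Atf3 and Dnajc1 kept theirs in 1 each. Fitted on the 6 libraries alone, 1 gene was called, shared with the 5, and with the replicate number as a block 17 were, 5 of them shared.

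Dex acted within 2 h. Averaged over the genotypes, 908 genes rose and 715 fell, of which 180 rose and 68 fell more than 2-fold (6 Dex and 6 vehicle libraries). The strongest rises were in Amica1, an adhesion molecule of leukocytes (40.2-fold; log2 5.33 ± 0.31), Ddit4, an inhibitor of mTORC1 (37.8-fold; 5.24 ± 0.25), Fkbp5, a co-chaperone that restrains the glucocorticoid receptor (19.6-fold; 4.29 ± 0.23), Socs2, a suppressor of cytokine signalling (3.99 ± 0.21), and Zbtb16, a zinc finger transcription factor (3.76 ± 0.16). Fkbp5 went from 14.8 ± 2.66 to 345 ± 29.2 CPM in WT and from 20.04 ± 1.81 to 332 ± 32.8 CPM in KO. The strongest falls were in the immediate early gene Egr2 (-3.21 ± 0.24), the transcriptional repressor Prdm1 (-2.91 ± 0.14), Enc1 (-2.56 ± 0.22), the chemokine Ccl4 (-2.33 ± 0.19) and Tnf (-2.22 ± 0.13). Each of these 10 changes had an adjusted p of at most 2.96e-11 (edgeR quasi-likelihood, Benjamini-Hochberg).

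Of 23 glucocorticoid receptor targets measured, 16 rose and 3 fell at 2 h (17 and 3 adjusted over the list alone). The list test called them (adjusted p = 1.08e-19, limma camera), also with an estimated correlation (adjusted p = 1.55e-05). Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose by 2.90 ± 0.15, the clock gene Per1 by 2.53 ± 0.12, Klf9 by 2.16 ± 0.13 and the phosphatase gene Dusp1 by 2.15 ± 0.15. The transcriptional repressor Bcl6 (-0.85), the G protein regulator Rgs2 (-0.72) and the acyl-CoA synthetase Acsl1 (-0.24; called in 5 of 12 fits without 1 library) fell. Of 16 inflammatory cytokines and chemokines 9 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation). Il1b fell by 2.48 ± 0.43, Ccl2 by 1.87 ± 0.31 and Ccl3 by 1.42 ± 0.14. Of 20 immediate early and MAPK feedback genes 10 fell and 4 rose (11 and 4 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). Ier3, Ier5 and Atf3 fell (-1.93 ± 0.12, -1.20 ± 0.07 and -1.04 ± 0.06), and the MAP kinase phosphatases Dusp1, Dusp2 and Dusp6 and the transcription factor Fos rose. In the Ms4a family 5 of 9 genes rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), Ms4a4a by 0.76 ± 0.15, Ms4a6b by 0.89 ± 0.12 and Ms4a6c by 0.57 ± 0.10. The Ms4a6 genes are similar copies between which the counting could split reads. Of 17 genes of the glucocorticoid-associated macrophage phenotype 6 rose (6 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation). Cd163, the haemoglobin scavenger receptor, rose by 1.69 ± 0.23 and the efferocytosis receptor Mertk by 0.76 ± 0.09. Of 22 cholesterol synthesis genes 3 fell (3 adjusted over the list alone; adjusted p = 0.985 with an estimated correlation). Nr3c1, the glucocorticoid receptor itself, fell by 0.28 ± 0.06. Il6 and Nos2 were not analysed here.

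At 8 h the response was broader, with 3071 genes up and 2758 down, 505 and 355 of them more than 2-fold. Fkbp5 stood 72.7-fold above vehicle (log2 6.18 ± 0.25), Strip2, of the striatin-interacting complex, rose by 6.67 ± 0.24, Zbtb16 by 4.95 ± 0.17 and Tsc22d3 by 3.71 ± 0.15. Amica1 and 3 other genes rose from levels near the limit of detection, with Amica1 at 9.80 ± 0.34 on the log2 scale. Hif3a, a hypoxia-inducible factor subunit, the hyaluronan receptor gene Lyve1 and Angptl7 had 0 to 8 counts over the 3 libraries of a vehicle group, so no fold is given for them. Strong falls that passed were in the immune checkpoint gene Cd276 (-3.19 ± 0.24), the MAP kinase phosphatase Dusp4 (-3.08 ± 0.19), the urokinase gene Plau (-3.06 ± 0.25) and the fractalkine receptor Cx3cr1 (-3.01 ± 0.36). Their adjusted p was at most 9.48e-09 (edgeR quasi-likelihood, Benjamini-Hochberg; 6 Dex and 6 vehicle libraries).

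The glucocorticoid receptor targets were again mostly up at 8 h, with 16 of 23 higher and 3 lower (16 and 3 adjusted over the list alone; adjusted p = 0.0086 with an estimated correlation). Per1 rose by 3.24 ± 0.13, Klf9 by 3.20 ± 0.14 and Dusp1 by 2.85 ± 0.16, and Bcl6, Rgs2 and the insulin receptor substrate Irs2 fell. In the Ms4a family 7 of 9 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.0846 with an estimated correlation). Ms4a4a rose by 3.43 ± 0.16, which is 10.8-fold, Ms4a6b by 2.54 ± 0.12, Ms4a6c by 2.07 ± 0.11 and Ms4a6d by 1.47 ± 0.09. Of the 17 genes of the glucocorticoid-associated macrophage phenotype 10 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). Cd163 rose by 3.11 ± 0.23, the transglutaminase gene F13a1 by 3.20 ± 0.19, the mannose receptor gene Mrc1 by 1.54 ± 0.10 and Mertk by 1.37 ± 0.09. The annexin Anxa1, the interleukin 1 receptor antagonist Il1rn and the cytokine Tgfb1 fell. Inflammatory cytokines and chemokines fell in 10 and rose in 2 of 16 (10 and 2 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). Il1b, Tnf, Ccl4 and Ccl2 fell (-3.03 ± 0.45, -2.93 ± 0.15, -2.74 ± 0.19 and -2.63 ± 0.32), and the cytokines Osm and Il18 rose by 0.90 and 0.34. Immediate early and MAPK feedback genes fell in 15 and rose in 3 of 20 (15 and 3 adjusted over the list alone; adjusted p = 0.415 with an estimated correlation). Etv5, a target of ERK signalling, fell by 1.74 ± 0.14 and Atf3 by 1.47 ± 0.06, while Dusp1, Fos and Ier2 rose.

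Metabolic and clock genes moved by 8 h as well. Of 22 cholesterol synthesis genes 14 fell and 0 rose (14 and 0 adjusted over the list alone; adjusted p = 0.415 with an estimated correlation). The epoxidase gene Sqle, Idi1, Msmo1 and Cyp51 fell (-1.45 ± 0.13, -1.41 ± 0.11, -1.13 ± 0.07 and -1.10 ± 0.09). Of 17 circadian clock genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). Per2 rose by 4.21 ± 0.22, Nfil3 by 2.54 ± 0.11 and Cry1 by 2.05 ± 0.10, and the clock transcription factors Bhlhe40, Bhlhe41, Npas2 and Nr1d2 fell. Of 18 oxidative stress genes under the transcription factor NRF2 10 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.959 with an estimated correlation). The thioredoxin reductase Txnrd1, the peroxiredoxin Prdx1 and the sulfiredoxin Srxn1 fell (-1.18 ± 0.11, -1.05 ± 0.08 and -0.89 ± 0.10), while the glutathione reductase Gsr, the haem oxygenase Hmox1 and the cystine transporter Slc7a11 rose. Of 31 interferon-stimulated genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.959 with an estimated correlation). Ifit1 fell by 1.77 ± 0.28 and Rtp4 by 1.32 ± 0.19, and the DNA sensor Ifi204 rose by 0.73 ± 0.09.

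By 24 h, 2991 genes were up and 2993 down, 431 and 666 of them more than 2-fold. Amica1 rose 181-fold (log2 7.50 ± 0.27), the haemoglobin-binding acute-phase protein gene Hp 94.8-fold (6.57 ± 0.25), the acute-phase gene Saa3 45.8-fold (5.52 ± 0.26), while Fkbp5 rose by 5.09 ± 0.24 and Strip2 by 5.41 ± 0.29 on the log2 scale. Tsc22d3 was up by 2.81 ± 0.14, Zbtb16 by 3.70 ± 0.16 and Ms4a4a by 3.03 ± 0.16, which is 8.16-fold. Pcp4l1 (-3.67 ± 0.17), the eotaxin receptor gene Ccr3 (-3.58 ± 0.28), the macrophage elastase gene Mmp12 (-3.39 ± 0.24) and the gene of the NF-kB inhibitor Tnip3 (-3.17 ± 0.22) were among the strongest falls. These falls had an adjusted p of at most 7.38e-13 (edgeR quasi-likelihood, Benjamini-Hochberg; 6 Dex and 6 vehicle libraries). KO vehicle 24 h replicate 2 stood apart from the other vehicle libraries at this time, as described further on, and without it 2798 genes rose and 3004 fell. Without it the log2 rises were larger for Amica1 (7.87), Hp (7.12), Saa3 (6.06), Fkbp5 (5.64), Ms4a4a (3.30) and Tsc22d3 (3.03). Those of Strip2 (5.18) and Zbtb16 (3.67) were smaller.

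Every one of the 32 measured cell cycle genes fell at 24 h (32 adjusted over the list alone; median log2 -1.91; adjusted p = 0.0807 with an estimated correlation). The replication helicase genes Mcm5, Mcm2 and Mcm6 had log2 changes of -2.70 ± 0.13, -1.86 ± 0.10 and -1.51 ± 0.07, and cyclin E1, Ccne1, of -2.04 ± 0.11. Of 12 monocyte markers 7 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). F13a1 rose by 4.05 ± 0.19 and Ly6c2 by 3.42 ± 0.14, and the monocyte receptor Ccr2, the nuclear receptor Nr4a1, Spn and Treml4 fell, Spn being called in 8 of 12 fits without 1 library. Of 13 MHC class II and costimulation genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.63 with an estimated correlation). H2-Eb1, H2-Aa and H2-Ab1, which present peptides to helper T cells, fell (-2.55 ± 0.17, -2.08 ± 0.15 and -1.72 ± 0.11), and the costimulatory ligand Icosl rose by 1.02 ± 0.09. Interferon-stimulated genes fell in 24 and rose in 1 of 31 (24 and 1 adjusted over the list alone; adjusted p = 0.694 with an estimated correlation). Ifit3, Ifit2 and Rtp4 fell (-2.43 ± 0.28, -2.10 ± 0.25 and -1.71 ± 0.19), and Ifi204 rose by 0.67. Cholesterol synthesis genes fell in 16 and rose in 1 of 22 (18 and 1 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). The regulator Srebf2 fell (-1.20 ± 0.09), and the isomerase Ebp rose by 0.20.

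The lists that were called at 2 h were called again at 24 h. Of the 23 glucocorticoid receptor targets 17 were higher and 3 lower (17 and 3 adjusted over the list alone; adjusted p = 0.0256 with an estimated correlation), the lower ones being Bcl6, Rgs2 and the stress sensor Sesn1. In the Ms4a family 7 of 9 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation). Ms4a6b stood at 2.03 ± 0.12, Ms4a6d at 1.59 ± 0.09 and, against the rest, Ms4a14 at -0.69 ± 0.08. Inflammatory cytokines and chemokines fell in 9 and rose in 1 of 16 (9 and 1 adjusted over the list alone; adjusted p = 0.675 with an estimated correlation). Tnf, Ccl7 and Il1b fell (-2.37 ± 0.15, -2.28 ± 0.37 and -1.74 ± 0.41) and Il18 rose. Immediate early and MAPK feedback genes fell in 13 and rose in 3 of 20 (13 and 4 adjusted over the list alone; adjusted p = 0.518 with an estimated correlation). Dusp4 fell by 2.72 ± 0.20 and Etv5 by 2.21 ± 0.14, while Dusp1, Ier2 and Ier3 rose. Of 17 genes of the glucocorticoid-associated macrophage phenotype 10 rose and 5 fell (10 and 5 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). The decoy interleukin 1 receptor Il1r2 rose by 2.72 ± 0.20 and Mertk by 1.22 ± 0.09, and Anxa1, Folr2, Il10, Il1rn and Tgfb1 fell. Markers of fibroblasts moved with this comparison, with 8 of 9 up and 0 down (8 and 0 adjusted over the list alone; the list was not called). Col1a1 went from 3.14 ± 1.32 to 8.42 ± 6.45 CPM in WT and from 3.43 ± 1.16 to 8.45 ± 2.40 CPM in KO, and was called in 11 of 12 fits without 1 library.

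The genes that answered Dex overlapped between WT and KO cells beyond the share of independent lists. In WT 1007, 4131 and 4655 genes changed at 2, 8 and 24 h, and in KO 1160, 4298 and 4275. Fitted on the WT libraries at 24 h alone, the count was 3101, 3075 of them shared. At 2 h 466 genes rose and 240 fell in both genotypes, where 37.6 and 16.4 would be shared by independent lists. At 8 h 1915 rose and 1604 fell in both, against 454 and 345, and at 24 h 1593 rose and 1799 fell in both, against 421 and 471. Genes called in opposite directions numbered 0, 0 and 1. Fkbp5 rose 23.2-fold in WT and 16.6-fold in KO at 2 h, and Tnf changed by -2.06 ± 0.19 and -2.37 ± 0.19 on the log2 scale.

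The difference of the Dex effect between KO and WT, tested gene by gene as an interaction, was called for 0 genes at 2, 8 and 24 h and for 0 averaged over the times, by edgeR quasi-likelihood and by DESeq2. At an unadjusted p under 0.05 stood 986, 133, 564 and 598 genes. For Ms4a4a the difference in log2 effect was 0.61 ± 0.30, 0.64 ± 0.30 and -0.43 ± 0.29 at the 3 times, the last of which was 0.15 without KO vehicle 24 h replicate 2 and -0.75 without replicate 3. Over the Dex-responsive genes, the median difference in response between KO and WT was 0.0268 at 2 h (1623 genes), 0.0141 at 8 h (5829 genes) and -0.0282 at 24 h (5984 genes), in log2 units along the direction of each gene's average change, and limma's fry did not call it at any time. Scored per library, the differences were 0.0235 ± 0.0315, 0.0171 ± 0.0235 and -0.0299 ± 0.0493 (SE; exact permutation p = 0.515, 0.56 and 0.685, two-sided, 3 libraries a group). Without KO Dex 2 h replicate 3 the interaction was called for 7 genes at 2 h, and the median difference at 2 h became 0.0766 and was called by fry. Without WT vehicle 24 h replicate 3 the difference at 24 h became -0.0568 and was called. The sign turned at 2 h without WT vehicle 2 h replicate 2 (-0.00384) or WT Dex 2 h replicate 2 (-0.000266), and at 24 h without KO vehicle 24 h replicate 2 (0.00786).

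**Figure D3:**
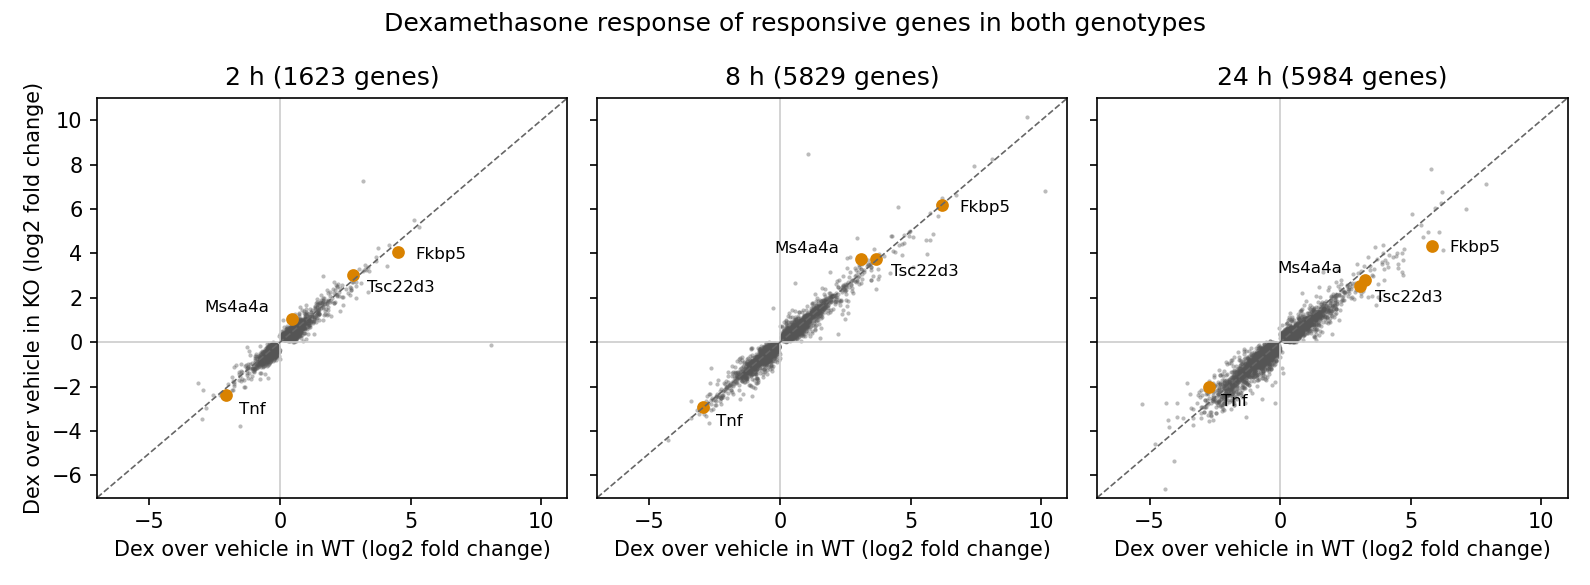
Log2 fold change of Dex over vehicle in WT on the horizontal axis and in KO on the vertical axis, with a point for each gene that changed in the average of the genotypes (1623, 5829 and 5984 genes at 2, 8 and 24 h), a dashed line of equal change, and Fkbp5, Tsc22d3, Tnf and Ms4a4a in orange. Correlations across genes called in either genotype, which are not independent replicates, were 0.914, 0.971 and 0.952, and over all genes 0.690, 0.946 and 0.924.

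A vehicle library stood between the treatments. In KO vehicle 24 h replicate 2, Fkbp5 was at 69.9 CPM against 14.2 and 16.9 CPM in the other replicates. Tsc22d3 was at 529 against 311 and 187 CPM, Ms4a4a at 179 against 93.0 and 53.5 CPM, and Per1 at 11.3 against 6.36 and 5.26 CPM. Zbtb16 was not raised, at 1.56 against 1.03 and 2.28 CPM. Amica1 was at 3.85 against 2.20 and 0.603 CPM, far below its mean of 323 CPM after 24 h of Dex in KO. Of the 457 genes that Dex induced more than 2-fold in WT at 24 h, 70.0% lay above both other replicates, and of the 665 it repressed 73.4% lay below both, against at most 39.2% and 60.8% for any other untreated or vehicle library. Without this library the Ms4a4a difference between KO and WT after 24 h of vehicle was -1.20 and passed (adjusted p = 0.000401, edgeR quasi-likelihood, Benjamini-Hochberg), the average without Dex became -1.19, and 25 genes differed without Dex, 22 of them shared. The KO response to 24 h of Dex then held 4011 genes.

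**Figure D4:**
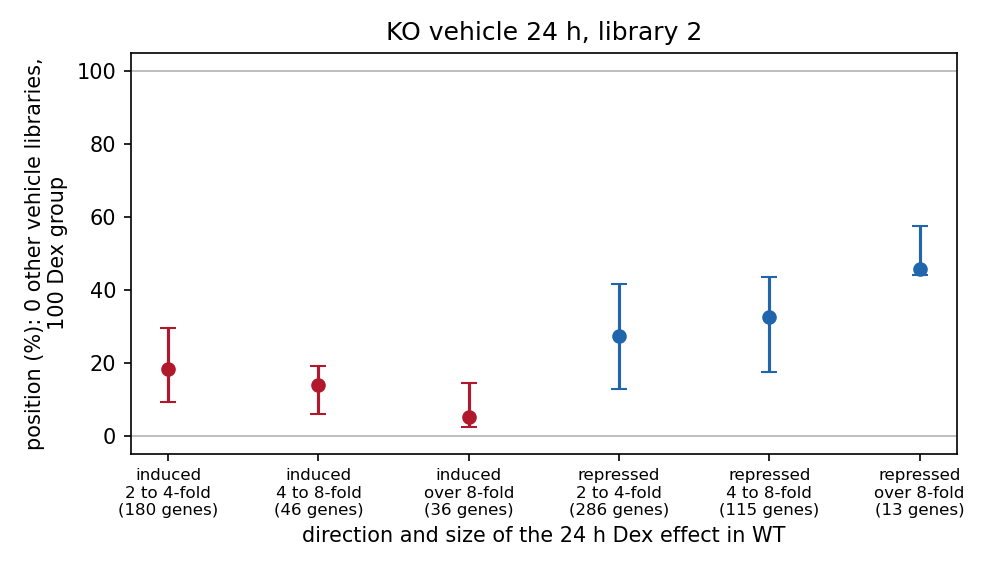
Position of KO vehicle 24 h replicate 2 between the mean of the other KO vehicle 24 h libraries (0%) and the mean of the KO Dex 24 h libraries (100%), as the median and quartiles over genes, by direction and fold of the Dex effect in WT at 24 h, for the 262 induced and 414 repressed genes that reached 5 CPM and differed at least 2-fold the same way between those KO means. The median was 18.1% for the 180 genes induced 2- to 4-fold, 5.16% for the 36 induced over 8-fold and 45.8% for the 13 repressed over 8-fold.

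The vehicle libraries, set against the untreated cells, show what changed with time in culture and with vehicle together. At 2 h 785 genes rose and 750 fell, at 8 h 948 and 1078, and at 24 h 1745 and 1719, of which 116 rose and 253 fell more than 2-fold (6 vehicle and 6 untreated libraries). Fosb, an immediate early gene, was up by 4.12 ± 0.28 at 2 h, with Spsb1 by 2.33 ± 0.23 and the inhibitory SMADs of TGF-beta signalling, Smad7 and Smad6, by 2.00 ± 0.26 and 1.97 ± 0.33. At 8 h Pald1 rose by 1.97 ± 0.31 and Nptx1 by 1.82 ± 0.25, and at 24 h the lipase inhibitor Angptl4 by 2.19 ± 0.17, Ctla2a by 2.08 ± 0.26, the sulfotransferase Sult1a1 by 1.94 ± 0.20 and the sorting receptor Sort1 by 1.79 ± 0.14. The 24 h values include KO vehicle 24 h replicate 2, without which 1534 genes rose and 1489 fell. Fitted on the libraries compared alone, the count at 2 h was 1007, 973 of them shared.

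Interferon-stimulated genes fell throughout this time course. Of 31 members 27 fell at 2 h (28 adjusted over the list alone; median log2 -0.58; adjusted p = 0.233 with an estimated correlation). All 31 fell at 8 h (31 adjusted over the list alone; median -1.89; adjusted p = 0.00356 with an estimated correlation) and at 24 h (31 adjusted over the list alone; median -2.33; adjusted p = 0.011 with an estimated correlation). Ifit1 stood at -1.38 ± 0.25 at 2 h and at -2.86 ± 0.27 at 8 h, where Ifit3 and Ifit2 had fallen as well (-3.06 ± 0.26 and -3.05 ± 0.24). At 24 h the regulator Irf7 fell by 3.98 ± 0.17, the nucleic acid sensor Zbp1 by 3.34 ± 0.12 and Oas1a by 2.14 ± 0.08. Slfn1 and Ms4a4c were lower still at 24 h (-5.27 ± 0.27 and -4.44 ± 0.22; adjusted p at most 6.92e-17, edgeR quasi-likelihood, Benjamini-Hochberg). MHC class II and costimulation genes fell in 10 of 13 at 8 h (11 adjusted over the list alone; adjusted p = 0.138 with an estimated correlation). At 24 h 11 of the 13 fell and the peptide-loading factor H2-DMb2 rose (11 and 1 adjusted over the list alone; adjusted p = 0.0341 with an estimated correlation). H2-Eb1 fell by 1.58 ± 0.15, H2-Ab1 by 1.55 ± 0.10 and Cd86 by 1.09 ± 0.12, while H2-DMb2 was called in 6 of 12 fits without 1 library.

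**Figure D5:**
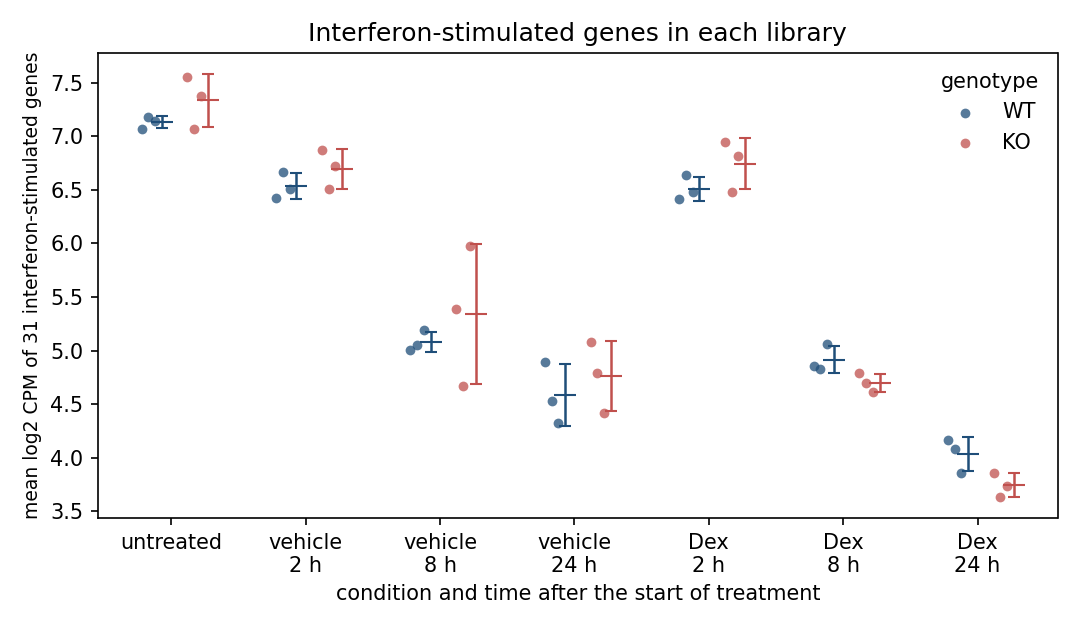
Mean log2 CPM of the 31 interferon-stimulated genes, with a point for each library and the mean ± SD of the 3 libraries of each group, for WT and KO in the 7 conditions. The median member fell by 1.89 at 8 h and by 2.33 at 24 h of vehicle against untreated cells.

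Other lists went both ways over the same hours. Oxidative stress genes under NRF2 rose in 8 of 18 at 2 h (8 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation) and in 14 at 8 h (15 adjusted over the list alone; adjusted p = 0.0539 with an estimated correlation). At 24 h 12 rose and the ferritin gene Fth1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). Gclc, of glutathione synthesis, was up by 0.94 ± 0.11 and Hmox1 by 1.04 ± 0.13 at 8 h. At 24 h 14 of 22 efferocytosis and complement genes rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 0.0421 with an estimated correlation). Mertk rose by 0.92 ± 0.09 and Stab1 by 0.74 ± 0.07, and the receptor kinase Axl and the complement genes C3 and Cfb fell. Of 18 fatty acid oxidation and PPAR targets 10 rose and 0 fell at 24 h (10 and 0 adjusted over the list alone; adjusted p = 0.0123 with an estimated correlation). Plin2, which coats lipid droplets, rose by 0.77 ± 0.07 and the uncoupling protein Ucp2 by 0.65 ± 0.07. Cholesterol synthesis genes fell in 19 of 22 at 24 h (19 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation), with Idi1 at -0.87 ± 0.11 and Cyp51 at -0.73 ± 0.09. The integrated stress response genes rose in 9 of 21 at 2 h (13 adjusted over the list alone; adjusted p = 0.0633 with an estimated correlation), with Cebpb at 1.15 ± 0.14. Genes of the Ms4a family fell in 6 of 9 at 8 h (7 adjusted over the list alone; adjusted p = 0.0539 with an estimated correlation). At 24 h 6 fell and Ms4a4a rose by 1.07 ± 0.15 (6 and 2 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation). Of 9 fibroblast markers 3 rose at 24 h (3 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation).

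Further lists were called after 24 h of vehicle. Of 13 mitochondrial transcripts 11 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation), with mt-Nd5 at 0.55 ± 0.05. Inflammatory cytokines and chemokines fell in 9 and rose in 0 of 16 (10 and 0 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation), with Ccl2 at -2.01 ± 0.31. Of 32 cell cycle genes 9 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). Of 17 genes of the glucocorticoid-associated macrophage phenotype 9 rose, and Il1r2 and Il1rn fell (10 and 2 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation). Of 23 glucocorticoid receptor targets 8 rose, and Rgs2 and the cell cycle inhibitor Cdkn1a fell (8 and 2 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation). That call had an adjusted p of 0.0416 (limma camera), and of 0.0660 without the libraries numbered 2, 0.0502 without those numbered 3 and 0.0546 with the replicate number as a block. Of 20 p53 targets and apoptosis genes 12 fell and Sesn1 rose (13 and 2 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation). Also called, and lost with an estimated correlation, were at 2 h the lists of glucocorticoid receptor targets, the NF-kB pathway, immediate early genes, cholesterol synthesis, glycolysis, the circadian clock and the Ms4a family (adjusted p of at least 0.233, limma camera). At 8 h these were the lists of inflammatory genes, cell cycle, glycolysis, heat shock, p53 targets and mitochondrial transcripts (adjusted p of at least 0.294, limma camera).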

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

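The tests on the spread of the library scores, within replicate numbers, within each treatment and on leaving out single libraries were chosen only after the result was seen; the list tests themselves were planned. The results below stand here because the list test with a preset correlation called the Dex effect different between KO and WT, in log2 units as the list's median of KO minus WT. None of them was called with an estimated correlation, and none of the members differed gene by gene (edgeR quasi-likelihood and DESeq2 called 0 genes, while 986, 133, 564 and 598 stood at an unadjusted p under 0.05 at 2, 8 and 24 h and in the average).

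For the interferon-stimulated genes the median KO minus WT Dex effect was -0.534 at 8 h (limma camera adjusted p = 2.46e-22, and adjusted p = 0.473 with an estimated correlation). It was -0.516 at 24 h (limma camera adjusted p = 1.47e-09 and 0.796) and -0.341 in the average over the times (7.71e-10 and 0.988). The list was not called at 2 h, where KO minus WT of the Dex effect on its mean log2 CPM was 0.0694 ± 0.200 (SE). Set against the spread between libraries, the score of the list differed at 8 h by -0.479 ± 0.390 (SE), with a Dex effect of -0.644 in KO and -0.165 in WT, and the exact permutation p was 0.23, so spread between single libraries remains a candidate explanation. Single libraries moved it either way: without KO vehicle 8 h replicate 3, whose score was 5.97 against 5.38 in replicate 1 and 4.67 in replicate 2, 34.4% of the difference was left, and without replicate 2 it grew to -0.815, or 170%. At 24 h the difference in score was -0.470 ± 0.276 with an exact permutation p of 0.11, and within replicate numbers 1, 2 and 3 it was -0.485, -0.708 and -0.216 (SE 0.142; exact sign-flip p = 0.25, the lowest that 3 pairs can give), against -0.454, 0.245 and -1.23 at 8 h. A lower interferon tone under Dex in KO cells, the biological reading, stays open: under Dex the score was lower in KO than in WT in each number at 8 h (4.79, 4.70 and 4.61 against 4.86, 4.83 and 5.06) and at 24 h (3.86, 3.64 and 3.74 against 4.16, 4.09 and 3.86), each with an exact permutation p of 0.1, the lowest that 3 against 3 can give, and not at 2 h (0.235 ± 0.152; exact permutation p = 0.2), so the mixed sign at 8 h came from the vehicle libraries.

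The other lists were called with smaller medians. At 2 h these were lysosome and phagocytosis genes (0.0864; limma camera adjusted p = 0.0184, and 0.511 with an estimated correlation) and mitochondrial transcripts (0.237; 0.0184 and 0.960). At 8 h they were cell cycle genes (-0.104; 0.0185 and 0.984) and the integrated stress response (-0.105; 0.00370 and 0.640). At 24 h they were oxidative stress genes under NRF2 (0.183; 0.00292 and 0.868), the heat shock and unfolded protein response (0.221; 6.24e-05 and 0.796) and mitochondrial transcripts (-0.196; 0.00212 and 0.868). In the average over the times they were cell cycle genes (-0.102; 0.0158 and 0.988), lysosome and phagocytosis genes (0.0552; 0.00326 and 0.214) and oxidative stress genes (0.1002; 0.0117 and 0.988).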

How the results depend on the processing

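The filter at a mean of 5 CPM, the block without KO vehicle 24 h replicate 2, the summed sets and the Ms4a4a level without that library were chosen only after the results were seen. Counts of genes differing between KO and WT depended on the processing. With the replicate number as a block they became 3 in untreated cells, 2, 4 and 1 after 2, 8 and 24 h of vehicle, 5, 1 and 17 after 2, 8 and 24 h of Dex and 111 in the average without Dex, of which 25 were shared with the unblocked fit; without KO vehicle 24 h replicate 2 the block gave 1 at 24 h of vehicle and 101 in the average. With the counts summed by genotype and number over the 4 conditions without Dex, the average gave 0 genes, and 0 with the replicate block. The targeted gene Ms4a4a was therefore missed by both. DESeq2 gave 2 and 2 after 2 and 8 h of vehicle, 4 and 25 after 2 and 24 h of Dex and 71 in the average. Fits on the compared libraries alone gave 1 in untreated cells, 2 after 2 h of vehicle, 1 after 8 h and 1 after 24 h of Dex. The cause was not tested, apart from the smaller number of libraries in the last fits. Fits on the compared libraries alone also gave 3101 genes for Dex in WT at 24 h and 1007 for vehicle at 2 h. Median-ratio scaling and the stricter filter kept every count of calls within 1.5 times. The setting with no filter used the same genes, as the filter had removed 0, so it is no separate check.

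Leaving out each library in turn gave 0 to 0 genes in untreated cells, 0 to 1, 0 to 3 and 0 to 14 after 2, 8 and 24 h of vehicle, 0 to 2 and 0 to 13 after 2 and 24 h of Dex, 9 to 38 in the average without Dex and 0 to 7 for the interaction at 2 h. Dex in the average of the genotypes ranged from 1467 to 1595, 5439 to 5644 and 5566 to 5881 genes, and vehicle against untreated from 1210 to 1505, 1472 to 2451 and 2932 to 3513. The difference in response size ranged from -0.00384 to 0.0766 at 2 h, with -0.000266 without WT Dex 2 h replicate 2, and from -0.0568 to 0.00786 at 24 h, and with the block and without KO vehicle 24 h replicate 2 it was 0.00262. The difference of the Ms4a4a response at 24 h was 0.147 without KO vehicle 24 h replicate 2 and -0.753 without replicate 3; the cause of these turns was not tested. Of 159 list calls 16 held with an estimated correlation, 157 with median-ratio scaling and 153 with the block, while 35, 21 and 26 were lost without the libraries numbered 1, 2 or 3, 2 of them with the opposite direction without number 1. Of the 55 list calls on genotype or interaction, 24, 44 and 39 held without number 1, 2 or 3 and 0 with an estimated correlation.

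Same-numbered libraries correlated with a median of 0.195 over 273 pairs, against -0.101 over 546 pairs of other numbers, and 41 of 42 libraries correlated best with their own number, a hint from the data that is not stated in the design. In the comparisons where the numbers paired the libraries, the block changed no other call of a named gene than those given with the results. Depth ran from 10140200 to 33528400 counts, and a 1.5-fold interaction was recovered in 29.9% of simulated genes at 8 h, so interactions of that size could go unseen.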

Other observations

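Markers and metabolic genes outside the lists called also moved with 24 h of Dex, averaged over the genotypes. Among 22 efferocytosis and complement genes 8 rose and 7 fell (9 and 7 adjusted over the list alone): the complement component C1qa rose by 2.19 ± 0.15 on the log2 scale and the receptor kinase Axl fell by 2.02 ± 0.13. Among 12 alternative activation genes 5 rose and 5 fell (5 and 6 adjusted over the list alone), with the chitinase-like gene Chil3 up by 3.74 ± 0.29. Of 22 glycolysis and hypoxia genes 5 rose and 15 fell (5 and 16 adjusted over the list alone), the regulator Pfkfb3 up by 1.87 ± 0.10 and pyruvate kinase, Pkm, down (-0.52 ± 0.05). Of 20 heat shock and unfolded protein response genes 10 rose and 3 fell (10 and 3 adjusted over the list alone), Herpud1 by 1.39 ± 0.10 and the chaperone Hspa5 by 0.54 ± 0.06. Of 21 integrated stress response genes 9 rose and 11 fell (9 and 11 adjusted over the list alone), with the mitochondrial folate enzyme Mthfd2 at -2.54 ± 0.15, and of 20 NF-kB pathway genes 5 rose and 9 fell (5 and 9 adjusted over the list alone), with the survival factor Birc3 at 1.61 ± 0.09. None of these lists was called by limma camera at 24 h.

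Markers of other myeloid cells went both ways at 24 h of Dex. Of 8 neutrophil markers 2 rose and 1 fell (2 and 1 adjusted over the list alone), with the collagenase Mmp8 up 8.84-fold (log2 3.14 ± 0.11) and the siderophore-binding Lcn2 by 3.44 ± 0.34. Of 8 dendritic cell markers 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Tcf4 at 0.56 ± 0.05 and the integrin Itgax at -2.16 ± 0.21. Of 7 osteoclast markers 1 rose and 2 fell (1 and 3 adjusted over the list alone), the phosphatase Acp5 at 1.26 ± 0.16, against the fusion receptor Dcstamp at -3.90 ± 0.45 and the integrin Itgb3 at -2.27 ± 0.12. Pdgfrb, among the 9 fibroblast markers of which 8 rose, was up by 1.79 ± 0.42 (list median 1.43; limma camera adjusted p = 0.0926, and adjusted p = 0.73 with an estimated correlation).

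The tests of KO vehicle 24 h replicate 2, of chromosomal segments and of whole sets of libraries were chosen only after the result was seen, whereas those of reads shared between copies, of the level of Ms4a4a and of other splits of the libraries were set before. KO vehicle 24 h replicate 2 lay between vehicle and Dex. RNA of the KO Dex 24 h group mixed into it would move every induced gene by a like share. Genes induced over 8-fold lay at a median of 5.16% of the way (quartiles 2.29 to 14.4%) and those induced 2- to 4-fold at 18.1% (9.32 to 29.4%). This argues against mixing from that group, and mixing from other Dex groups was not tested. A Dex library under a wrong label would put induced genes near 100%, and their 90th percentile was 35.5%, which argues against that too. Of the 414 repressed genes placed this way 78.7% lay below both other replicates, and of the 262 induced 82.1% lay above both. The placing used those replicates, which favours such shares, and over all 665 repressed and 457 induced genes they were 73.4 and 70.0%. On the placed genes WT vehicle 24 h replicate 3 had 64.7% of the repressed below and 34.4% of the induced above its other replicates. Partial glucocorticoid exposure of that culture may account for the library, as a hypothesis found and tested on the same data.

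Counted gene by gene, the genes that differ between KO and WT without Dex lie together more often than random sets of expressed genes. With 1 gene kept of each similar pair, 6 of 22 had another within 1 Mb (permutation p = 0.0046, 10000 random sets). The genes kept of the 2 similar pairs adjoin on chromosome 12 and were still counted as neighbours of each other. The others counted were Lyrm7, Gpx3, Slc36a1 and G3bp1 on chromosome 11, and the 95th percentile of the random sets was 4. Whether the genes exceed random sets with the adjoining pairs counted once was not tested. With all copies kept 8 of 24 had a neighbour (permutation p = 0.0010). In the longer list called with the replicate block 31 had a neighbour (permutation p = 0.0054). Sets of 22 genes called for Dex, taken in order of p, reached 6 in 1 of 71 at 2 h, 0 of 254 at 8 h and 1 of 262 at 24 h, and sets of 24 reached 8 in 0 of them at each time, so a strain segment away from Ms4a4a is a candidate explanation, although neighbours regulated together stay open as well, since the 22 genes with the lowest p for Dex had counts of 2, 2 and 6 at 2, 8 and 24 h (permutation p = 0.34, 0.34 and 0.0046). Of the called genes 0 lay within 10 Mb of Ms4a4a, which argues against a strain segment around it as the source of these neighbours. Such a segment is not excluded, since it need not change expression. Reads moved between the copies of a pair would not raise both. Both copies were higher in KO in each pair summed, which argues against such moves for these pairs. The sums then had to be higher as well and add no separate support. Their differences were 0.50 for Srp54a and Srp54b and 0.77 for Fam177a and 1700047I17Rik2. Whether these differences follow the level of Ms4a4a cannot be told apart, because at 24 h of Dex their median was 0.847 of that without Dex, with few libraries behind it; an effect of MS4A4A itself stays open.

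Other splits of the same libraries were fitted on the compared libraries alone. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. KO against WT gave 1 gene in untreated cells, 2 and 1 after 2 and 8 h of vehicle, 0 at 24 h, 0 and 1 after 2 and 8 h of Dex and 1 at 24 h, the highest other splits gave 2, 1, 1, 2, 1, 1 and 7, and 4, 1, 4, 10, 10, 3 and 5 of the 10 splits gave as many. Among the 4 splits that part all 3 same-numbered pairs, the highest others gave 0, 0, 1, 1, 0, 1 and 0 in the same order. For Dex against vehicle in WT and KO at each time the real split was the 1 of 10 with as many genes. The highest other gave 0. Over 50 splits for Dex in the average of the genotypes, the real split was the 1 of 50 as large at each time. It gave 1450, 6290 and 5358 genes at 2, 8 and 24 h, against at most 1, 0 and 0 in the others. For vehicle against untreated it was the 1 of 50 as large too, with 1007, 1550 and 2490 genes against 0. This argues against chance only with each library as a sample of its own. Each set of a genotype and number holds libraries of both conditions compared, so splits of whole sets cannot test these comparisons. For KO against WT without Dex the real split was the 1 of 50 as large too (22 genes against at most 1), but those splits exchange single libraries. With sets of libraries of a genotype and number kept whole, 6 of 10 splits gave as many. The split of WT 1, WT 2 and KO 1 against WT 3, KO 2 and KO 3 gave 1102, which points to a structure of the samples. Every other split that reached 22 kept the 2 sets of at least 1 number on the same side. Among the 4 splits that part all 3 same-numbered pairs, the real one gave 22 genes and the others 5, 2 and 0. With 4 such splits the share cannot go under 0.05, so differences between sets remain a candidate explanation and chance is not excluded. For the interactions at 2, 8 and 24 h and in the average the real count was 0, so that all 50 splits give as many whatever the data and the comparison decides nothing; the highest others gave 3, 10, 143 and 3. The split with 143 genes parts the 24 h vehicle libraries by the same numbers as the set split with 1102, and its cause was not tested further.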
